A study of Homo sapiens with 6 samples.

How the data were processed

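RNA was measured in 6 libraries of H7, an established human embryonic stem cell line that was grown on Matrigel in mTeSR Plus medium per the labels' protocols. Of these, 3 libraries came from control cells and 3 from cells of a SAMD4A knockdown line. Per the labels' protocols, total RNA was taken with Trizol, RNA was accepted above a set integrity number, and libraries were made with the TruSeq Stranded mRNA kit and read as paired ends on an Illumina NovaSeq instrument. Such a kit selects messages by their poly-A tail, so RNA without a tail is poorly sampled. The construct used for the knockdown is not given in the sources used here.

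The deposited table holds raw counts, which are whole numbers of read pairs or reads assigned to each gene by the authors, with no normalization. The submitters' processing notes name HISAT2, HTSeq and the genome build GRCh38. Versions, counting options and the strand setting are not given in the sources used here, so genes that overlap on opposite strands and near-identical copies (metallothioneins, HSPA1A and HSPA1B, histones, tubulins) are uncertain as single genes. The table has 60664 Ensembl genes, of which 29398 had a count of 0 in all 6 libraries, and each gene carries the symbol, type and coordinates that the authors deposited. Exon lengths in the table, an annotation column the authors deposited, were used only for a check on length. All count columns in the table were matched to the samples by name.

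Library totals ran from 19270688 to 21355171 counts. The biological coefficient of variation between replicates was 7.47%, and counting error weighs more for genes with few counts. Replicate libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 2.77 to 7.90 within groups and 52.4 to 60.5 between groups, so no library was a repeat of another. Nothing in the labels says that replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

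Counts were analysed with R 4.3.3. Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16, which left 17258 genes, and libraries were scaled with TMM factors. Groups were compared with the edgeR quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Levels are given as TMM-scaled CPM, the counts of a gene per 1e+06 counts of its library, as mean and SD over 3 libraries, and log2 fold changes are knockdown over control with a standard error (SE) derived from the fold change and its F statistic. The 30 gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and adjustment over the lists. Alternatives were an estimated correlation per list, the rotation test fry, DESeq2 1.42.0, limma-voom, other scaling factors, other low-count filters, the replicate number as a block, and each library left out in turn. An offset for GC content and length, the removal of mitochondrial and the 10 most abundant genes, the list counts without knockdown replicate 1, and the estimated correlation without that library were chosen after the data were seen. Over-represented annotation terms were not tested, since the test was planned only for a table that carries such terms.

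The scripts were tested on simulated counts for the comparison of knockdown with control, over 16965 genes. The edgeR test recovered 62.9% of genes changed 1.5 fold and 73.7% of genes changed 2 fold, and 97.0% of the latter among genes with a mean count of at least 100. The last restriction was set after a first run showed that low-count genes held the overall share down. Of 144 calls 10 were false. Only 196 of the simulated genes were changed, while 51.7% of the tested genes were called in the real data. Recovery and false calls depend on that share, so these rates may not carry over. The list test called the list that had been moved and 0 others. Simulated genes varied independently of each other, while estimated correlations in the real lists reached 0.45. That run therefore cannot show how often the list test calls lists falsely when their members vary together.

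The samples, tests, lists and alternatives were fixed before the data were examined. The rule for named genes took SAMD4A, its paralog SAMD4B, POU5F1, NANOG, SOX2 and FGF2. It then took the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean CPM of at least 1, a full gap between the groups and a gene symbol, and the 5 highest and 5 lowest by adjusted p. From each list that passed its test or had at least 3 called members it took the 4 members with the smallest adjusted p, leaving out mitochondrial and Y-linked genes and XIST. It gave 132 genes. Some of them are not reported here. Other genes are named as chosen after their values were seen. Hairpins were searched in the 3′ UTR of 1 coding transcript per gene in GENCODE 29.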

Results

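Poly-A RNA of H7 human embryonic stem cells was sequenced in 3 control libraries and 3 libraries of a SAMD4A knockdown line. SAMD4A is an RNA-binding protein of the Smaug family, whose members repress and destabilise the messages they bind. The series asks what SAMD4A does in self-renewal and lineage specification of these cells. Totals were 19896813, 19270688 and 20070027 counts in control replicates 1 to 3, and 21355171, 20664743 and 19588021 in knockdown replicates 1 to 3. Mitochondrial genes took 3.39% ± 0.08 of the counts in control and 5.03% ± 0.14 in knockdown (SD, n = 3 each).

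SAMD4A itself (ENSG00000020577, chromosome 14, 54566117 to 54793315, GRCh38) was lower in every knockdown library than in every control library. Its level was 52.7 ± 3.08 CPM in control and 28.1 ± 0.66 CPM in knockdown (SD, n = 3 each), a log2 fold change of -0.90 ± 0.07 (SE, edgeR adjusted p = 9.0e-08). The 3 knockdown libraries held nearly equal SAMD4A levels, 27.4, 28.5 and 28.5 CPM. SAMD4B, the paralog of SAMD4A, rose from 148 ± 10.8 to 244 ± 9.22 CPM, a log2 fold change of 0.72 ± 0.06 (edgeR adjusted p = 5.0e-08).

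The genes of the pluripotency core moved little. POU5F1, the transcription factor OCT4, had a log2 fold change of 0.19 ± 0.05 (edgeR adjusted p = 0.0024), and NANOG had one of -0.25 ± 0.07 (edgeR adjusted p = 0.011). SOX2 did not pass the test, at -0.02 ± 0.04 (edgeR adjusted p = 0.70). FGF2, a growth factor that these cells need to stay undifferentiated, fell from 263 ± 4.25 to 170 ± 7.50 CPM, a log2 fold change of -0.63 ± 0.05 (edgeR adjusted p = 3.9e-08). The POU5F1 call was lost with scaling by total counts only (0.03, edgeR adjusted p = 0.55) and SOX2 then passed at -0.18 (edgeR adjusted p = 0.0027). The NANOG call was lost without control replicate 3 (edgeR adjusted p = 0.054).

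**Figure D1:**
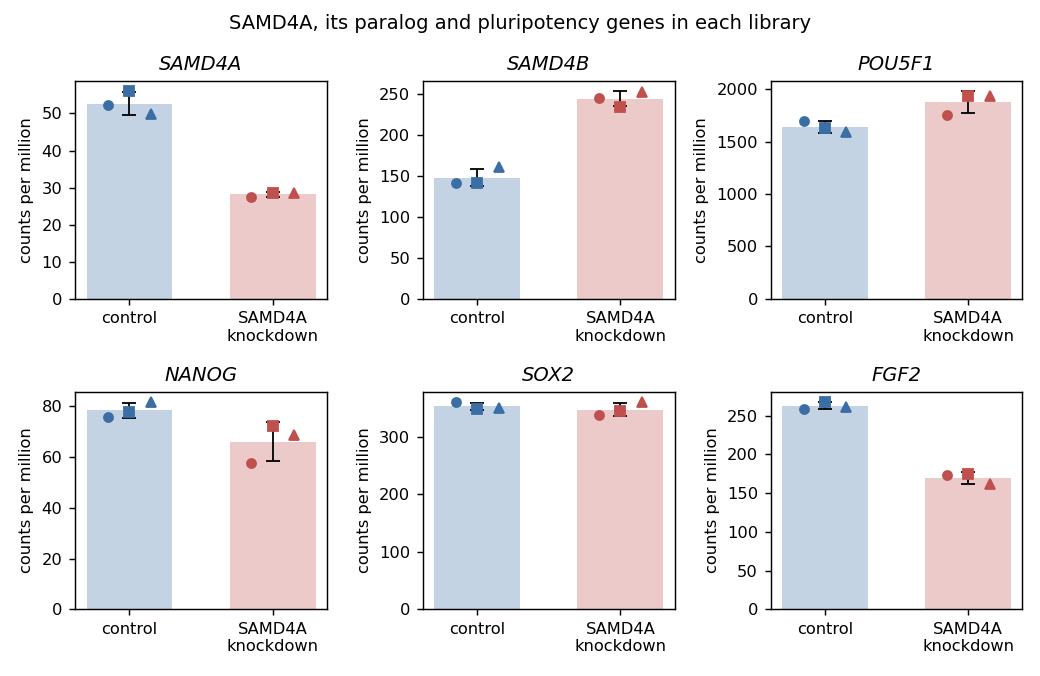
TMM-scaled CPM (y axis, from 0) of SAMD4A, SAMD4B, POU5F1, NANOG, SOX2 and FGF2 in control and SAMD4A knockdown libraries; bars are means, error bars the SD and points the 3 libraries of a group (circle, square and triangle for replicates 1, 2 and 3). SAMD4A lies at 52.7 CPM in control and 28.1 CPM in knockdown, and SOX2 at 353 and 348 CPM.

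Over all genes, 8926 of 17258 tested genes (51.7%) passed the threshold, 4503 higher and 4423 lower in knockdown. A change of at least 2 fold was found for 1516 genes, 463 higher and 1053 lower. Among protein-coding genes 7931 of 14178 passed, and among long noncoding RNAs 683 of 2029. Most changes were small, with a median size of 0.49 on the log2 scale. The groups did not overlap in 58.3% of the tested genes, where chance gives 10%. With scaling by total counts only, 2704 genes were higher and 6410 lower, and the median of all genes moved from -0.01 to -0.17.

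The 12 largest rises, among genes with a mean of at least 1 CPM and a full gap between the groups, included 3 HSP70 genes. HSPA8, a constitutive HSP70 chaperone (ENSG00000109971, chromosome 11, 123057489 to 123063230), rose from 264 ± 3.41 to 2468 ± 87.4 CPM, a log2 fold change of 3.23 ± 0.04 (edgeR adjusted p = 1.7e-16). The stress-inducible HSPA1A and HSPA1B, which are near-identical copies and uncertain as single genes, had log2 fold changes of 3.25 ± 0.16 and 2.96 ± 0.13. HMGCS1, an early enzyme of sterol synthesis, rose by 2.79 ± 0.13 and INSIG1, a regulator of that pathway, by 2.34 ± 0.09. GDF3, a TGF-beta family ligand of pluripotent cells, rose by 3.09 ± 0.16, the long noncoding RNA LINC-ROR by 2.80 ± 0.18 and DPPA3, a gene of naive cells and germ cells, by 3.24 ± 0.54. EVPL, HTR1A, HS3ST2 and TNMD, which like DPPA3 (0.19 CPM) were below 1 CPM in control, had log2 fold changes of 2.87, 2.84, 2.62 and 2.49. TUBB4B (1.57), HSPA5 (1.35) and DNAJA1 (1.56) were among the 5 rises with the smallest adjusted p.

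The 12 largest falls by the same rule included 3 metallothionein and 3 histone genes. The smallest adjusted p among the falls were those of TRIB3, TSC22D3, INHBE, CHAC1 and DHRS2. TRIB3, a pseudokinase induced by amino acid and endoplasmic reticulum stress (ENSG00000101255, chromosome 20, 362835 to 397559), went from 223 ± 7.40 to 24.8 ± 1.49 CPM, a log2 fold change of -3.17 ± 0.06 (edgeR adjusted p = 1.2e-14). SLC30A2, a zinc exporter, had a log2 fold change of -5.68 ± 0.45 and was below 0.20 CPM in each knockdown library. The metallothionein genes MT1H, MT1E and MT1G on chromosome 16 had log2 fold changes of -4.56, -4.05 and -4.02, and the histone genes H2BC11, H2BC17 and H2BC18 of -4.20, -4.14 and -3.89. OR2B6 (-5.84) and OR2W6P (-5.69), an olfactory receptor gene and a pseudogene, lie on chromosome 6 in the region of H2BC17 but do not overlap it. H2BC17 ends at 27893891, and OR2W6P starts at 27937465 and OR2B6 at 27957241. Whether their counts include reads of other genes was not tested. OR2B6, OR2W6P and SLC30A2 had at most 5 counts in each knockdown library, so the size of their falls is uncertain. G0S2, an inhibitor of fat breakdown, fell by 4.12, DHRS2 by 3.73 and TSC22D3, a glucocorticoid-induced gene, by 2.77. INHBE fell by 2.32 and CHAC1, a glutathione-degrading enzyme, by 1.87. NPIPA2 (-3.98) belongs to a family of near-identical copies.

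**Figure D2:**
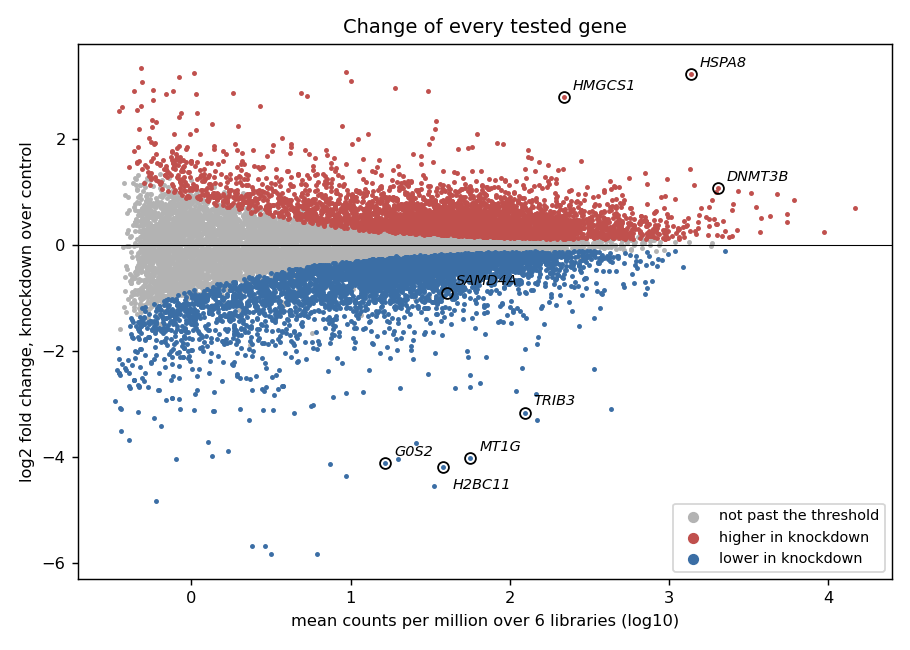
Log2 fold change of knockdown over control (y axis) against the mean CPM over the 6 libraries (x axis, log10) for all 17258 tested genes; red and blue points passed the threshold as higher or lower, grey points did not. Circles mark named genes, with HSPA8 at 3.23 and TRIB3 at -3.17.

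Of the 30 gene lists, 11 passed the list test, 6 toward higher and 5 toward lower levels. None passed with an estimated correlation (lowest adjusted p = 0.37 with an estimated correlation, lowest unadjusted p = 0.019), and 13 passed with fry, the same 11 and 2 more. Camera asks whether members move more than other genes, and fry only whether they move. With so many genes changed, fry passes lists more easily, so it adds no weight to the camera calls. Member counts below are over all genes tested, and those adjusted over the list alone are given where they differ.

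Sterol synthesis genes rose together: 21 of 24 were higher, 0 lower (median log2 fold change 0.95, camera adjusted p = 7.0e-11; adjusted p = 0.37 with an estimated correlation). SQLE, a rate-limiting enzyme of the pathway, rose by 1.66 ± 0.06 and DHCR7, which makes cholesterol from its last precursor, by 1.25 ± 0.05. All 13 messages encoded in mitochondria were higher (median 0.70, camera adjusted p = 1.9e-07; adjusted p = 0.37 with an estimated correlation). Of nuclear genes of oxidative phosphorylation 16 of 30 were higher, 17 when adjusted over the list alone, and 0 lower (median 0.20, camera adjusted p = 0.00014; adjusted p = 0.37 with an estimated correlation), with ATP5MC1 at 0.91, SDHB at 0.70, NDUFA2 at 0.75 and SDHC at 0.49. Of cytosolic ribosomal proteins 28 of 30 were higher, 29 adjusted over the list alone (median 0.22, camera adjusted p = 1.3e-06; adjusted p = 0.55 with an estimated correlation). RPL23 rose by 0.72, RPS15 by 0.65, RPS3 by 0.57 and RPS27 by 0.51. With total counts only the median was 0.05 for oxidative phosphorylation and 0.06 for ribosomal proteins.

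Cell cycle genes were mostly higher. In the S phase list 18 of 24 rose and 1 fell, 18 and 2 adjusted over the list alone (median 0.46, camera adjusted p = 1.1e-05; adjusted p = 0.52 with an estimated correlation). The nucleotide reductase subunit RRM2 rose by 1.26, the polymerase clamp PCNA by 1.14, FEN1 by 1.04 and MCM4 by 0.69. In the G2 and M phase list 16 of 23 rose and 3 fell (median 0.23, camera adjusted p = 0.0056; adjusted p = 0.89 with an estimated correlation), with CCNB1 at 1.17, UBE2C at 0.56, CDC20 at 0.49 and MKI67 at 0.39. With total counts only the median of the G2 and M phase list was 0.07 (camera adjusted p = 0.043). Replication-dependent histone genes went the other way, with 11 of 15 lower and 0 higher (median -0.90, camera adjusted p = 0.00057; adjusted p = 0.37 with an estimated correlation). H2AC6 had a log2 fold change of -3.30, H2BC12 of -2.71 and H2BC5 of -1.73. These messages mostly lack a poly-A tail, so the libraries sampled only their tailed part.

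The list of the integrated stress and unfolded protein responses split. Of 24 members 16 were lower and 7 higher (median -0.76, camera adjusted p = 0.018; adjusted p = 0.37 with an estimated correlation). TRIB3, CHAC1 and ATF3 (-2.12), a stress transcription factor, were among the lower ones, while HSPA5, an endoplasmic reticulum chaperone, was higher by 1.35. With total counts only the call was lost (camera adjusted p = 0.12) while the median was -0.91. The list of heat shock and immediate early genes did not pass (camera adjusted p = 0.86) but passed with fry toward higher levels (adjusted p = 8.5e-05), with 8 of 20 members higher and 8 lower. Its higher members were led by HSPA8, HSPA1A, HSPA1B and DNAJB1 (1.25), and ATF3 and EGR1 were lower. Its median was -0.10 and its mean 0.19.

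FGF and MAPK targets and YAP targets were mostly lower. Of FGF and MAPK targets 15 of 24 fell and 3 rose, 16 and 3 adjusted over the list alone (median -0.40, camera adjusted p = 0.0024; adjusted p = 0.37 with an estimated correlation). PHLDA1 fell by 1.33, the immediate early gene EGR1 by 1.91, and the feedback inhibitors SPRY4 by 0.87 and DUSP6 by 0.78. The median of this list was -0.24 in knockdown replicate 1 and -0.51 in replicates 2 and 3. Of YAP targets 16 of 21 fell and 1 rose, 17 and 2 adjusted over the list alone (median -0.42, camera adjusted p = 0.00018; adjusted p = 0.52 with an estimated correlation). AJUBA fell by 1.45, IGFBP3 by 1.27, DLC1 by 1.10 and CCN2 by 1.09. Only 9 of the 26 trophoblast and amnion genes were tested. IGFBP3 of the YAP list is also among these, and TFAP2C is also in the naive list. Trophoblast and amnion genes were lower for 7 of 9 and higher for 1 (median -0.76, camera adjusted p = 0.038; adjusted p = 0.37 with an estimated correlation), with TFAP2C at -0.91, GABRP at -0.89 and KRT18 at -0.30. That call was lost without control replicate 1 (camera adjusted p = 0.072), control replicate 2 (0.072) or knockdown replicate 2 (0.056), and with total counts only (0.12), where the median was -0.91.

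**Figure D3:**
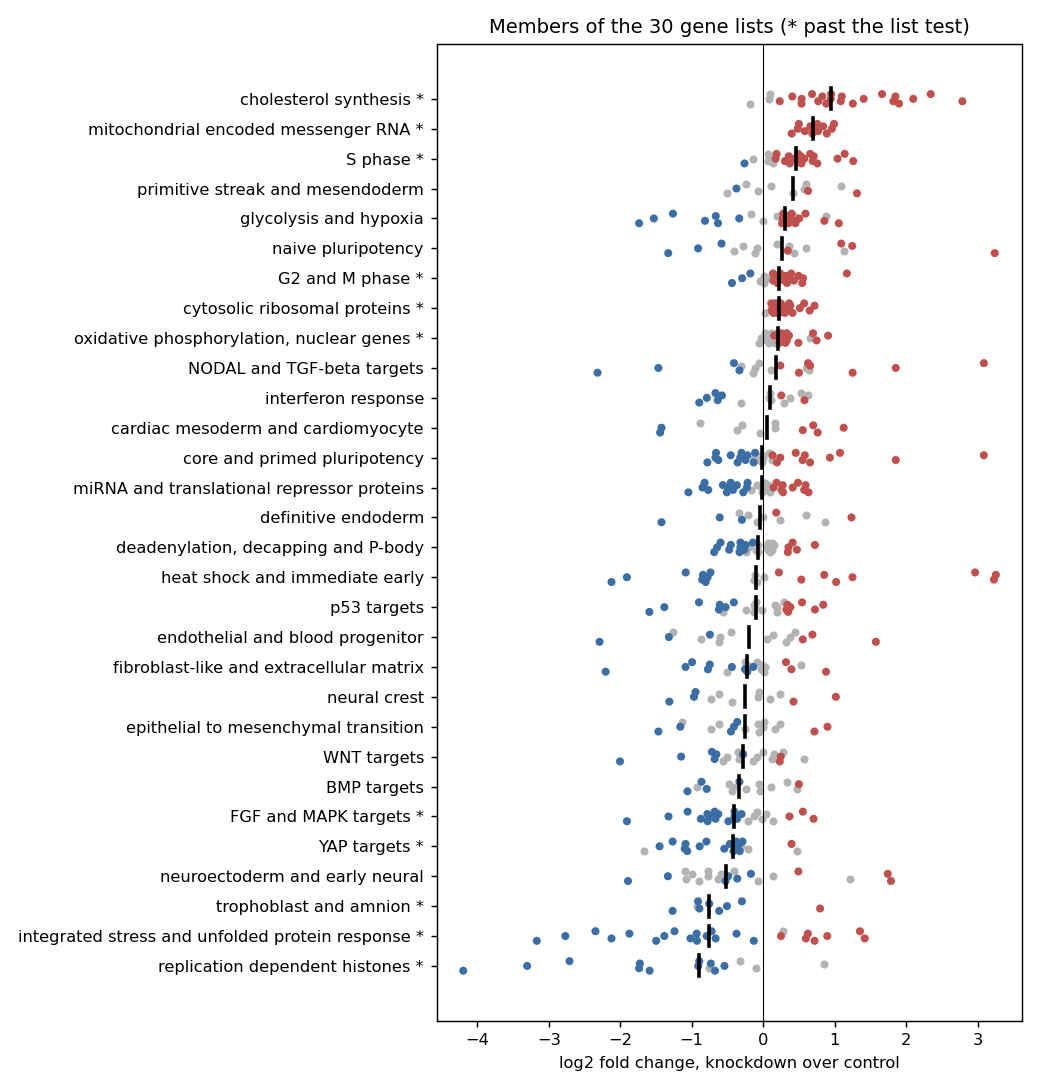
Log2 fold change of knockdown over control (x axis) of each tested member of the 30 lists (rows); red and blue points passed the threshold as higher or lower, grey points did not, and black ticks are list medians. Sterol synthesis lies at a median of 0.95 and replication-dependent histones at -0.90.

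Pluripotency lists did not move to 1 side. In the core and primed list 11 of 30 members were higher and 12 lower (camera adjusted p = 0.86; median -0.02, mean 0.16), and the list passed with fry toward higher levels (adjusted p = 0.0030). DNMT3B, a DNA methyltransferase of primed cells, rose by 1.07 ± 0.04 from 1296 to 2728 CPM, PRDM14 by 0.93 and GDF3 by 3.09, while DUSP6 was lower. In the naive list 4 of 16 were higher and 3 lower (camera adjusted p = 0.77). DPPA3, at only 0.19 CPM in control, had a log2 fold change of 3.24, ZFP42 one of 0.34, TFAP2C of -0.91 and KLF5 of -1.33. Of NODAL and TGF-beta targets 7 of 18 were higher and 4 lower (camera adjusted p = 0.86), with LEFTY1 at 1.85, GDF3 at 3.09 and INHBE at -2.32.

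Knockdown replicate 1 stood apart from the other knockdown libraries in genes of early neural tissue. Against the control mean, the median of the neuroectoderm list was 0.36 in knockdown replicate 1 and -0.78 in replicates 2 and 3. Over all 3 libraries 6 of 21 members were lower and 3 higher, 4 and 3 adjusted over the list alone (camera adjusted p = 0.42). Without knockdown replicate 1 the list passed (camera adjusted p = 0.00073; adjusted p = 0.25 with an estimated correlation), with 14 members lower and 3 higher; that test was planned, and the member counts without this library were added after seeing the data. SIX3, a forebrain transcription factor, was at 5.03 ± 0.23 CPM in control, 6.97 CPM in knockdown replicate 1, 0 in replicate 2 and 0.054 CPM in replicate 3. DLK1 was at 50.02 ± 4.33 CPM in control and at 75.7, 2.44 and 1.30 CPM in knockdown replicates 1, 2 and 3. SIX3 and DLK1 were chosen after their values were seen. Other members rose in all 3 knockdown libraries, among them NES (0.49), FEZF1 (1.79) and TUBB3 (1.74), and DCX fell by 0.49.

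**Figure D4:**
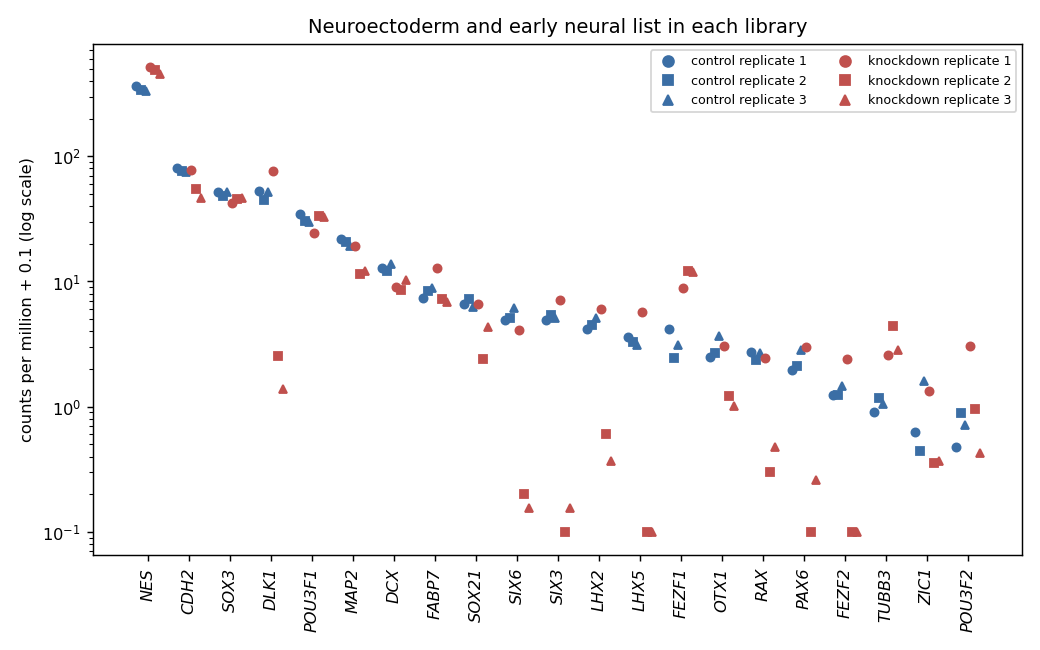
CPM plus 0.1 (y axis, log scale) of the 21 tested members of the neuroectoderm list (x axis) in the 6 libraries, blue for control and red for knockdown, with circle, square and triangle for replicates 1, 2 and 3. SIX3 lies at 6.97 CPM in knockdown replicate 1 and at 0 and 0.054 CPM in replicates 2 and 3.

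Lists that failed with all libraries and passed without knockdown replicate 1 were 4 further ones. Of WNT targets 6 of 19 were lower and 2 higher (camera adjusted p = 0.30), and 11 and 2 without that library (0.015), with WNT5B at -2.00, MYC at -0.68, NKD1 at -0.66 and FZD7 at 0.23. The FZD7 call was lost with total counts only (0.07, edgeR adjusted p = 0.18). Of BMP targets 4 of 15 were lower and 1 higher (camera adjusted p = 0.56), and 8 and 1 without it (0.029), with ID4 at -1.06, BMP7 at -0.86, ID3 at -0.79 and SMAD6 at 0.50. Of genes of the epithelial to mesenchymal transition 5 of 17 were lower and 2 higher (0.42), and 9 and 2 without it (0.017), with ITGA5 at -1.16, PLAUR at 0.90 and TNC at 0.72. Of fibroblast-like and matrix genes 9 of 21 were lower and 3 higher (0.32), and 12 and 3 without it (0.037), with CCN2 at -1.09, THBS1 at -0.996, COL6A3 at -0.77 and COL6A1 at 0.32. The medians of these lists in knockdown replicate 1 were 0.01, 0.10, 0.14 and 0.04 against the control mean, in that order, and -0.37, -0.39, -0.46 and -0.20 in replicates 2 and 3. With an estimated correlation and without that library, a run chosen after seeing the data, their adjusted p were 0.25, 0.39, 0.46 and 0.68.

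Other lineage lists did not pass. Primitive streak and mesendoderm genes were higher for 2 of 11 and lower for 1, 1 and 1 adjusted over the list alone (camera adjusted p = 0.93). Their median was 0.65 in knockdown replicate 1 and -0.12 in replicates 2 and 3. NODAL, at 12.1 CPM in that library and 6.11 and 5.72 CPM in the others, lost its call without it (0.20, edgeR adjusted p = 0.37). That call was also lost, at log2 fold changes of 0.47 to 0.58, with upper-quartile factors (edgeR adjusted p = 0.064), total counts only (0.13) and the GC and length offset (0.071), without control replicate 2 (0.15) or 3 (0.16), and with limma-voom (limma adjusted p = 0.068). FGF8 was at 1.31, FOXH1 at -0.37, and APLNR did not pass at 1.09 (edgeR adjusted p = 0.070). APLNR was at 0.88 CPM in control and at 3.74, 1.02 and 0.86 CPM in knockdown replicates 1, 2 and 3. Its log2 fold change was 0.10 without knockdown replicate 1 (edgeR adjusted p = 0.86), and it passed without replicate 2 (1.40, 0.026) or 3 (1.44, 0.019) and with no low-count filter (1.10, 0.0053). Definitive endoderm genes were higher for 2 of 12 and lower for 3 (camera adjusted p = 0.81; median -0.04, mean 0.01), with AFP at 1.23, FOXA3 at -0.61 and GATA4 at -1.42. Cardiac genes were higher for 4 of 12 and lower for 2 (camera adjusted p = 0.80, median 0.06, mean -0.08, with a median of -0.10 by total counts only). ACTC1 was at 0.70, KDR at 0.55, PDGFRA at 0.76 and GATA4, also in this list, at -1.42. The PDGFRA call was lost without control replicate 2 or 3 (edgeR adjusted p = 0.057 and 0.059) or knockdown replicate 2 or 3 (0.053 and 0.071), and with total counts only (0.056), at log2 fold changes of 0.60 to 0.77. Endothelial and blood progenitor genes were higher for 3 of 16 and lower for 3 (camera adjusted p = 0.94), with TEK at 0.69, LMO2 at -1.32 and SOX18 at -2.29. Neural crest genes were higher for 2 of 12 and lower for 3 (camera adjusted p = 0.63), with ETS1 at 1.02, B3GAT1 at 0.42, SOX9 at -0.95 and NGFR at -1.31.

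Regulators of message decay and translation moved both ways. Among proteins of deadenylation, decapping and P-bodies 5 of 30 were higher and 11 lower (camera adjusted p = 0.80), with CNOT9 at 0.35, PARN at -0.48 and DCP1A at -0.69. Among miRNA and translational repressor proteins 10 of 31 were higher and 13 lower (camera adjusted p = 0.80), with AGO1 at 0.63, DGCR8 at 0.59 and TNRC6C at -0.82. Of the glycolysis and hypoxia list 14 of 26 were higher and 7 lower, 14 and 8 adjusted over the list alone (camera adjusted p = 0.18). The glycolytic enzyme LDHA rose by 0.85, while VEGFA had a log2 fold change of -1.74, ADM of -1.26 and SLC2A3 of -0.81. Of p53 targets 7 of 25 were higher and 7 lower (camera adjusted p = 0.81), with BAX at 0.84, PMAIP1 at -0.61, SESN2 at -1.38 and GDF15 at -1.59. Of interferon response genes 2 of 15 were higher and 5 lower, 2 and 4 adjusted over the list alone (camera adjusted p = 0.94; median 0.09, mean -0.06, with a median of -0.07 by total counts only), with IFITM1 at 0.25, OAS3 at -0.67, MX1 at -0.64 and DDX60 at -0.90. The IFITM1 call was lost with total counts only (0.09, edgeR adjusted p = 0.19) and the OAS3 call without control replicate 1 (-0.60, edgeR adjusted p = 0.061).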

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

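The main alternatives were planned; the GC and length offset and the removal of abundant genes were chosen after seeing the data. The SAMD4A log2 fold change kept its call in every setting run, between -0.86 and -0.94 with any 1 library left out and at -1.06 with total counts only. The number of genes changed was 9629 without knockdown replicate 1 and 7409 to 7954 without any 1 other library. Changes of at least 2 fold numbered 1935 without knockdown replicate 1, in place of 1516. In log2 CPM that library had r = 0.984 with each other knockdown library, which had r = 0.991 between them. Genes changed numbered 8316 with DESeq2, 9014 with limma-voom and 8974 with the offset. With total counts only, genes higher numbered 2704 in place of 4503, because that scaling moved the median of all genes to -0.17. With an estimated correlation 0 lists passed in place of 11. With knockdown replicate 1 left out too, a run chosen after seeing the data, 0 passed. A larger correlation between genes is not the whole cause. The stress list had an estimated correlation of -0.03, below the preset 0.01, yet its unadjusted camera p rose from 0.0061 to 0.038. Other lists that had passed reached up to 0.45. The test with an estimated correlation also uses the few degrees of freedom of the libraries. With the preset correlation it uses the many of the genes. Fewer degrees of freedom raise p by themselves, so a lost call does not show that members vary together. How much each part weighs was not tested. Lists past the threshold numbered 9 with total counts only, 16 without knockdown replicate 1 and 10 or 11 without any 1 other library. Of 132 named genes 123 kept their side of the threshold in every setting that tested them and 0 reversed. FZD7, IFITM1, NANOG, NODAL, OAS3, PDGFRA and POU5F1 lost their call somewhere, and SOX2 and APLNR gained one. Replicate numbers gave no sign of pairing, with r of -0.02, -0.01 and -0.04 between deviations of same-numbered libraries. These values cannot show whether such libraries shared a day or culture, which the labels do not say. With the replicate number as a block 8434 genes and 11 lists passed. Enrichment of annotation terms was not run. Genes with few counts limit the calls, as the simulated recovery shows.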

Other observations

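Tests named here on the GC and length trend, abundant genes, the genes of knockdown replicate 1, the scaling and single libraries were chosen after the results were seen, as were the gene families, which were taken up because members stood out and so carry no p-value; the splits of the libraries and the hairpin test were planned before theirs were.

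Metallothionein genes were lower. Of 7 metallothioneins 6 were lower and 0 higher (median -2.36), 3 of 4 lower without the members among the largest falls, and their near-identical copies make single members uncertain. Of 19 zinc transporters 6 were higher and 7 lower: of 8 SLC30 exporters 6 were lower and 1 higher, and of 11 SLC39 importers 5 were higher and 1 lower. SLC30A1, SLC30A2 and SLC30A10 had log2 fold changes of -2.67, -5.68 and -1.63 and SLC30A3 one of 0.65, and SLC39A10 and SLC39A14 had 1.51 and -0.26. Of 17 cytosolic tRNA synthetases 11 were lower and 5 higher, with SARS1 at -1.08 and WARS1 at -0.92.

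Chaperones and tubulins were mostly higher. Of 17 HSP70 and HSP90 chaperones 11 were higher and 3 lower (median 0.72), and 7 and 3 of 13 without those picked by size or adjusted p. All 8 subunits of the CCT chaperonin, which folds tubulin and actin, were higher (median 0.19), and the median shrank to 0.03 with total counts only. Of 11 tubulins 9 were higher and 1 lower (median 0.53), and 8 and 1 of 10 without TUBB4B.

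Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split alone (1 of the 10) reached 8926 genes changed, 4503 higher, 4423 lower and 1516 changed at least 2 fold, and the highest other split gave 0 in each case. For lists, 3 of the 10 splits gave at least the real 11, and the highest other gave 15 while it called 0 genes. That split put knockdown replicate 1 with control replicates 1 and 2. Every other split keeps 2 libraries of a condition together on each side, and so part of the real difference, but the count of lists does not set the real grouping apart.

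The first pattern is the breadth of the change, 8926 of 17258 genes. A trend with GC content or length is argued against as its whole cause, since 91.3% of the calls kept their call and direction once each library's trend was removed. A few abundant genes that take more counts would move all other genes alike. None of 11 shifts of the knockdown libraries from -0.5 to 0.5 on the log2 scale left fewer calls than 100% of the 8926. This scan cannot decide the question, since TMM scaling had already centred the genes at a median of -0.01. With mitochondrial and the 10 most abundant genes left out, 99.6% of the calls kept their call and direction. This run cannot decide it either, since TMM factors already make up for such genes in the main fit. The balance of directions does rest on the scaling, with 2704 genes higher by total counts only in place of 4503. A difference in culture or harvest between control and knockdown may account for part of the 8926 calls and stays open beside an effect of the knockdown, since 1 knockdown line is named and the sources used here do not say whether libraries came from different clones, passages or days.

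The second pattern is the lower medians of the stress response and histone lists beside the higher median of the sterol list. The stress list itself split, with 16 of 24 members lower and 7 higher. The scaling of the libraries moves all genes alike and is argued against as the whole cause, since the sterol median lay at least 1.66 above the stress and histone medians in each knockdown library (SD over libraries at most 0.10). The size of each fall and rise does depend on it. A single deviating knockdown library is argued against, since the smallest of the 9 medians over lists and knockdown libraries was 0.69 in the shared direction. Nutrient state or density at harvest may differ between the lines and was not tested, and neither was an effect of SAMD4A on these genes.

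The third pattern is a set of genes, part of them in the neural list, that were low in knockdown replicates 2 and 3 and not in replicate 1. By a rule set after seeing the values, 28 genes at 2 CPM or more in control and replicate 1 were at least 4 fold lower in replicates 2 and 3. Their median against control was 0.42 (log2) in replicate 1. Of these genes 7 were in the neural list. The others included PRTG, GBX2, LGI1 and SEZ6L as well as ACTA2, ANKRD1, GREM1, COL2A1 and ADAMTS9, and were not sorted by tissue. For any other pair of libraries in a group 0 genes met the rule. The level of SAMD4A alone is argued against, since the neural list median was 0.36 in knockdown replicate 1, where SAMD4A was at 0.96 of its level in the other 2. Control cells or a swapped library would need a share of control signal near 1, and the upper quartile of that share over 169 genes changed at least 4 fold was 0.42 (median 0.13; a first bound of 0.1 on the median had been missed). A population of other cells, of fixed or varying makeup, may account for it and stays open, as do different clones, passages or days. A chi-square test of 1 shared ratio of replicate 1 to control over the 28 genes, beyond counting and replicate noise, gave p = 1.3e-16. It cannot decide against a fixed makeup, since the knockdown moves genes too. The spread between these genes (SD 0.37, log2) lay within that of random genes of like expression (0.30 to 0.70).

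A hypothesis from the known binding of Smaug proteins to hairpins with a CNGG loop is that messages with such a hairpin rise in the knockdown. Over 13803 genes with a 3′ UTR of at least 50 bases, 6336 had such a hairpin with a stem of 5 pairs. Within 50 bins of UTR length and GC content their mean log2 fold change exceeded that of the others by 0.0042 (95% interval -0.02 to 0.03, permutation p = 0.73). The reversed loop, meant as a control, gave a difference of 0.04 (permutation p = 0.0005), so differences of that size can arise without the motif. These data give no sign of a rise for this class of genes. The bound of 0.03 covers only the spread of the permutations, and the reversed loop exceeded it, so it sets no upper limit. Indirect changes of many genes, a partial knockdown, the higher SAMD4B level and the loose motif could hide an effect on fewer messages, beyond the 0.0042 measured.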
